A study of Sus scrofa with 6 samples.

How the data were processed

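Gene expression was measured in day 5 to 6 pig blastocysts (Sus scrofa), the hollow preimplantation embryo of trophectoderm and inner cell mass, on 6 arrays with 2 colours. All 6 sample labels give day 5. Per the labels, 3 biological replicate RNA samples were compared in a loop, each pair of RNA samples on 2 arrays with the Cy3 and Cy5 dyes exchanged. RNA samples 2 and 1 shared arrays 1 and 2, RNA samples 3 and 1 shared arrays 3 and 4, and RNA samples 3 and 2 shared arrays 5 and 6. Per the labels' protocols, RNA was isolated with a kit for very small samples, amplified in 2 rounds of T7 transcription, and the amplified RNA was labelled chemically with the dyes. The number of embryos behind an RNA sample, the scanner settings and the background correction are not given in the sources used here. All 6 arrays belong to 1 group, so no conditions were compared. Each RNA sample is 1 biological unit, so p-values measure the spread between hybridisations of the same RNA.

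The deposited table holds 1 value per probe and array for 20400 probes. The deposited values are log2 ratios of the 2 channels, as far as the values themselves show, and their scale and direction are not stated. Raised as a power of 2, 95.3% to 98.9% of the measured values of an array were ratios of whole numbers up to 5000, against 0.133% to 0.5% for the same values shifted by a small amount. A share of ratios were whole numbers, reciprocals of whole numbers or exactly 1 (within a relative tolerance of 1e-05), as arises where a channel without signal is set to a fixed low value. Apart from ratios of 1, 84.9% to 96.7% of these on an array were even numbers or their reciprocals. A floor of exactly 1 would not favour even numbers, so the value of the floor is not settled here. Such ratios were treated as not measured. They made up 64.3%, 48.4%, 2.00%, 1.02%, 33.5% and 2.68% of the probes on arrays 1 to 6. The median log2 ratio over all probes was -3, 0, 0.52, 0.64, 0.05 and -0.11 on arrays 1 to 6, so the columns had not been centred. Of the 32 ways to turn the sign of single arrays, a common direction on all 6 left the least outside the loop, 23.8% of the sum of squares against 27.5% for the next. That next way turned array 3 alone, and the one after it, with 32.4%, array 4 alone. Either would exchange the sample difference and the dye effect of the pair of RNA samples 3 and 1. Ratios were read as Cy5 over Cy3, which is likely because the labels list Cy5 first. If the authors took the reverse, every difference below turns its sign and the counts higher and lower change places, while sizes and total counts stay.

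The 5431 probes measured on all 6 arrays (26.6%) were tested. A transcript without signal in 1 RNA sample was thus left out of the reported setting, although it would differ between RNA samples. Each array was centred on its median over these probes, the 2 arrays of a pair were turned to a common direction and averaged, and the resulting 3 values per probe were fitted in limma 3.58.1 (R 4.3.3) with 2 coefficients and 1 residual degree of freedom. The design fixed before the data were examined took the values as deposited, with centring as an alternative. Centring, and the exclusion of floor values, became the reported setting once the columns proved uncentred, before any test was run, and the uncentred values became the alternative. Differences are thus relative to the median probe. Uncentred, the median differences were 1.25 for RNA samples 2 and 1, 0.23 for 3 and 1, and -0.92 for 3 and 2. Moderation gave all probes 1 common variance, so each difference had a standard error of 0.43. The fit also took the noise of the 3 pairs of arrays as equal, although their spread differed. P-values were adjusted by Benjamini-Hochberg over probes with a threshold of 0.05, and a moderated F test covered all 3 RNA samples. A fit of the 6 single arrays with a dye term, which has 3 residual degrees of freedom, is given beside it. In both fits a difference also draws on the other 2 pairs of the loop, so it can lie outside the values of its own 2 arrays.

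The scripts were tested on simulated data with 200 changed probes among 5431 in RNA sample 2, in 10 runs. In the comparison of RNA samples 2 and 1, the fit of pair averages recovered 20.5%, 93.8% and 99.7% of probes changed by 1, 2 and 3 log2 units, and 10.1% of its calls were false. The fit of the 6 single arrays had 6.60% false calls there. In the comparison of RNA samples 3 and 2, the shares of false calls were 10.3% and 6.75%. In the comparison of RNA samples 3 and 1, where nothing was changed, the fits made 2.2 and 0.6 calls per run, all of them false. The simulated noise of a probe had 1 SD on all 6 arrays. The spread of the real arrays differed, with a median absolute deviation of 0.65 on array 4 and 1.41 on array 1. The simulated shares are therefore no estimate of the false calls in the real data. The number of arrays limits the precision of every difference.

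Gene names came from a platform annotation that gave 178 of the 20400 probes 1 gene symbol (175 genes), none several symbols, and left 20222 unnamed here. All 178 gene identifiers were found in the RefSeq table of assembly Sscrofa11.1 with equal symbols. The chromosome of a gene was taken from it, and no coordinates were used. Of the named probes, 56 were tested. The genes named were fixed by a rule before the data were examined. It took the 10 genes with the largest fold in each direction of each comparison, among those past the threshold with both arrays of the pair in that direction. To these it added, from each list, up to 4 members past the F test or otherwise the 2 with the largest range, and the 5 further genes with the smallest F test p. Members of 22 gene lists were also fixed, for pluripotency, trophectoderm, primitive endoderm, maternal transcripts, cell junctions, conceptus signals, cell cycle, apoptosis, heat shock, antioxidants, glycolysis, respiratory chain, lipid metabolism, ribosomal proteins, chromatin, imprinting, sex-linked genes, cumulus cells, oviduct and uterus, blood and immune cells, fibroblasts and reference genes. Members were matched by identical symbol, which missed members named here by an older symbol, such as ATP5G1, now ATP5MC1, of the respiratory chain list. It also left IFN-DELTA-1 unmatched to IFND of the conceptus signals list. By identical symbol, 10 lists had a named probe and 2 had a tested gene, 1 each, so no set test was run. Alternatives covered centring, scaling, the handling of floor values, the model, the threshold, position on the array, loess (span 0.3) on the intensity recovered from the whole numbers, and leaving out each array. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.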

Results

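Transcript levels of 3 biological replicate RNA samples of day 5 to 6 pig blastocysts were compared on 6 arrays, 2 for each pair of RNA samples. The comparison asked how far replicate blastocyst RNA samples differed from one another, since the design held no treatment or second stage. Signal varied widely between arrays. On array 1, 62.3% of probes had the numerator of the ratio at the floor or equal to the other channel, against 0.343% on array 4. Both arrays of the pair 3 and 1 measured 19842 probes, those of the pair 3 and 2 measured 13381, and those of the pair 2 and 1 measured 6193.

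**Figure D1:**
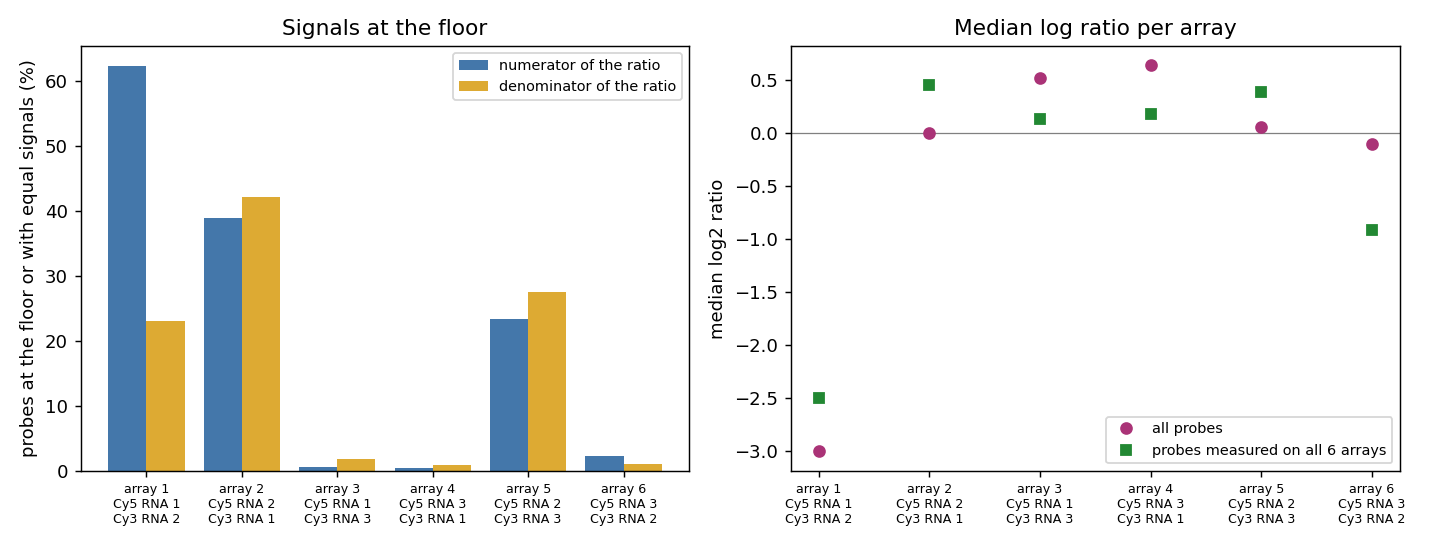
Signal per array. The left panel shows, for each of the 6 arrays, the percentage of the 20400 probes with the numerator (blue) or denominator (yellow) of the ratio at the floor or with equal signals in both channels, and the right panel the median log2 ratio over all probes (circles) and over the 5431 probes measured on all arrays (squares). Arrays 3, 4 and 6 have under 3% of such probes, and the median over all probes is -3 on array 1 against -0.11 to 0.64 on the others.

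Among the 56 tested probes with a gene name, 7 genes were past the threshold both between RNA samples 2 and 1 and between RNA samples 3 and 2, with RNA sample 2 above both others in 3 and below both in 4. SULT1E1, which encodes the oestrogen sulfotransferase, PPYR1, a receptor for pancreatic polypeptide, and CYSLTR2, a receptor for cysteinyl leukotrienes, were higher in RNA sample 2 than in both others. TSPO, an outer mitochondrial membrane protein linked to cholesterol transport, CALCRL, the calcitonin receptor-like receptor, OXTR, the oxytocin receptor, and HAPLN1, a link protein of the hyaluronan matrix, were lower. With the values uncentred, HAPLN1 turned to 0.07 between RNA samples 2 and 1, where CALCRL had -0.32 and OXTR -0.20, and none of these 3 passed. In the fit of single arrays, 3 of the 7 genes, TSPO, SULT1E1 and PPYR1, were past the threshold in both comparisons. Over all tested probes, 1184 of 5431 (21.8%) passed the moderated F test in limma at an adjusted p under 0.05, and 463 in the fit of single arrays, all of which were among the 1184. RNA sample 2 was farthest from the mean of the other 2 in 1030 of the 1184 (87.0%), RNA sample 3 in 112 and RNA sample 1 in 42. Both pairs with RNA sample 2 had a wide spread (SD of pair averages 1.00 and 0.98, against 0.31 for RNA samples 3 and 1). Noise of such spread would also favour RNA sample 2, and the share without differences was not computed. Differences between RNA samples took 86.9% of the sum of squares of the loop, where 66.7% is expected with no differences. The F test count depended on single arrays: it was 0 without array 1, 317 without array 2, 1813 without array 3, 238 without array 4 and 450 without array 5. With loess on intensity it was 233 of 4843 probes, against 952 of the same probes with centring. Over all probes with floor values it was 890 of 20400 (4.36%), and with pairs of 1 measured array kept 960 of 11462 (8.38%).

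Between RNA samples 2 and 1, SULT1E1 (probe 7302) had the largest absolute log2 difference among named genes, 3.25 ± 0.43 (SE), or 9.50-fold, with an adjusted p of 3.88e-11. Its 2 arrays gave 3.40 and 3.63. TSPO (probe 1252) was lower in RNA sample 2 by 8.70-fold, with a log2 difference of -3.12 ± 0.43 (SE) and an adjusted p of 2.62e-10, and its 2 arrays gave -3.45 and -3.51. In the fit of single arrays, without 1 common variance for all probes, the adjusted p was 0.00729 for SULT1E1 and 0.00802 for TSPO. Without array 1 neither passed, with values of 3.03 for SULT1E1 and -2.92 for TSPO (adjusted p 0.0748 for both). PPYR1 (1.81) and CYSLTR2 (1.74) were higher in RNA sample 2, as was INHA, the inhibin alpha subunit (1.58, adjusted p 0.0037). PPYR1 had 1.44 without array 1 and 1.58 without array 4, and did not pass in either case. CYSLTR2 fell to 1.09 without array 1 and to 1.02 without array 5, and had an adjusted p of 0.0869 in the fit of single arrays. The INHA difference came mostly from 1 array, as array 1 gave 4.50 and array 2 gave 0.38, and without array 1 the fitted value was 0.15. CALCRL (-1.53), OXTR (-1.41) and HAPLN1 (-1.14) were lower. CALCRL and OXTR rested largely on array 1, with -3.16 on array 1 and -0.34 on array 2 for CALCRL and with -3.23 and -0.04 for OXTR. Without array 1 the values were -0.82 and -0.91. In the fit of single arrays none of the 3 genes passed (adjusted p 0.0574, 0.0553 and 0.0602). With 1 of the 6 arrays left out in turn, CALCRL passed 3 times, OXTR 2 times and HAPLN1 1 time. SLC22A2, an organic cation transporter, passed the threshold at 1.17, but its arrays went opposite ways, 3.77 on array 1 and -0.60 on array 2. Of the 56 named genes, 5 were higher and 4 lower.

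Over the array, 585 probes were higher and 474 lower in RNA sample 2 than in RNA sample 1. The fit of single arrays gave 209 higher and 97 lower, all 306 among those of the pair fit. Of the 6193 probes measured on both arrays, 904 were at least 2-fold higher and 1021 at least 2-fold lower. The 2 arrays correlated at -0.20 across probes before they were turned, and probes are not independent replicates. With uncentred values the split was 2172 higher and 10 lower, and with equal spread 491 and 251. Loess gave 212 higher and 90 lower, and all 20400 probes with floor values gave 916 and 192. No probe passed without array 1 (1990 at an unadjusted p under 0.05), 377 passed without array 2, 195 without array 4 and 248 without array 5.

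Between RNA samples 3 and 2, TSPO was 13.0-fold higher in RNA sample 3, with a log2 difference of 3.70 ± 0.43 (SE) and an adjusted p of 7.51e-15, and its arrays gave 3.60 and 3.08. In the fit of single arrays its adjusted p was 0.00231. HAPLN1 (1.37), CALCRL (1.16), OXTR (1.13) and GOT1, the cytosolic aspartate aminotransferase (1.12), were also higher in RNA sample 3. GOT1 had arrays at 0.17 and 1.93 and OXTR at 0.24 and 1.56, and each passed in 2 of 10 alternatives. Without array 5 CALCRL fell to 0.56 and OXTR to 0.69, and GOT1 fell to 0.66 without array 2 and 0.72 without array 6. CALCRL, OXTR and GOT1 did not pass in the fit of single arrays (adjusted p 0.0884, 0.0713 and 0.108), and HAPLN1 did (0.0237), although it passed in 2 of the 6 fits with 1 array left out. With values as deposited HAPLN1 had 0.45, CALCRL 0.24, OXTR 0.21 and GOT1 0.21, and none of the 4 passed (adjusted p 0.382 to 0.666). SULT1E1 was lower by 6.84-fold, with a log2 difference of -2.77 ± 0.43 (SE), an adjusted p of 9.36e-09 and arrays at -3.19 and -1.83. Its adjusted p was 0.00588 in the fit of single arrays. CYSLTR2 (-2.10) and PPYR1 (-1.98) were lower as well. For CYSLTR2 array 5 gave -4.33 and array 6 gave -0.54, and its value was -0.66 without array 5, -1.77 without array 1 and -1.71 without array 4, none of them past the threshold. PAG6, a pregnancy-associated glycoprotein of a trophoblast gene family, was lower in RNA sample 3 (-1.38, adjusted p 0.0109), with arrays at -1.11 and -1.68. The remaining genes lower in RNA sample 3 were HCRT, the orexin precursor (-1.22), CD46, a complement regulator (-1.11), and CYP8B1, a sterol hydroxylase of bile acid synthesis (-1.10). HCRT had -0.44 on array 5 and -2.45 on array 6, and -0.66 without array 6. HCRT, CD46 and CYP8B1 did not pass in the fit of single arrays (adjusted p 0.0608, 0.0856 and 0.0646) or with centring within print blocks. PAG6 passed in the fit of single arrays (adjusted p 0.0484), and of its 10 alternatives 4 did not pass, those without array 1, 2, 4 or 5. In total 5 named genes were higher and 7 lower.

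**Figure D2:**
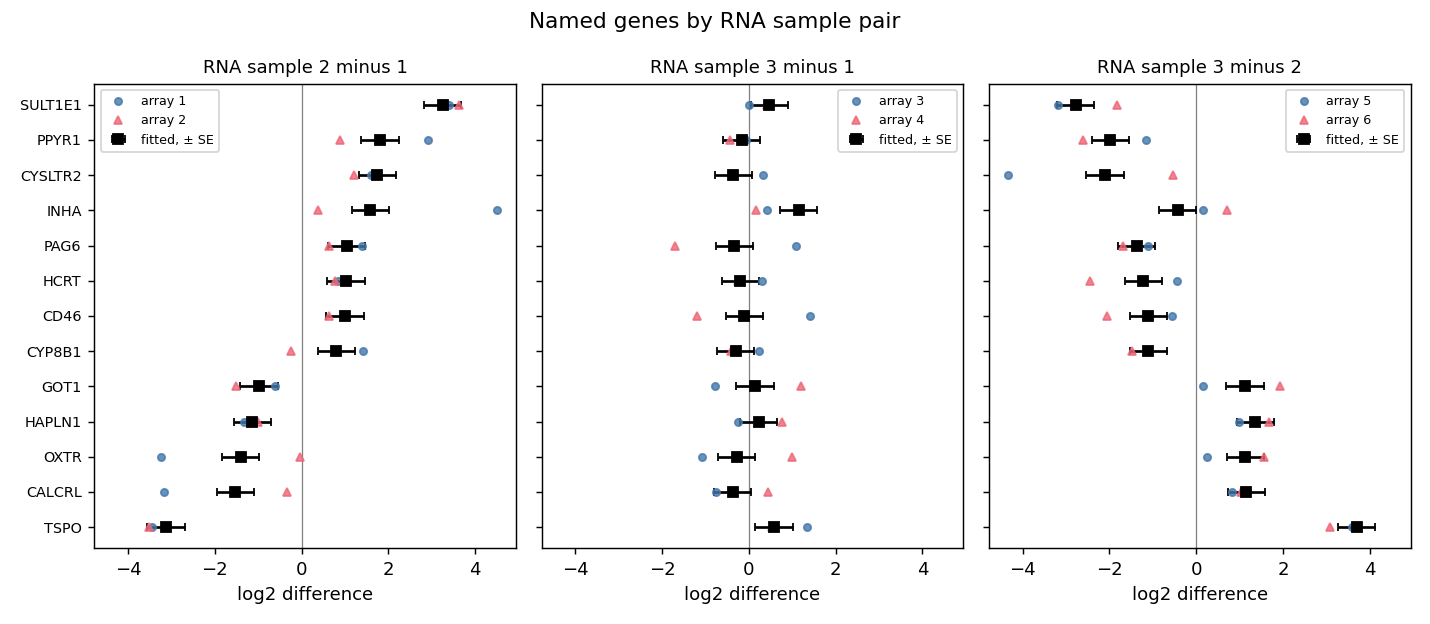
Named genes by pair of RNA samples. For the 13 genes that the rule took in any comparison, the x axis gives the log2 difference between RNA samples 2 and 1, 3 and 1, and 3 and 2, with black squares for the fitted difference ± SE and coloured symbols for the 2 arrays of each pair. TSPO lies at -3.12 and 3.70 in the outer panels and SULT1E1 at 3.25 and -2.77, while no gene passed the threshold in the middle panel.

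Over the array, 329 probes were higher and 794 lower in RNA sample 3 than in RNA sample 2. The fit of single arrays gave 98 and 558, with 653 probes called by both fits. Among 13381 probes measured on both arrays, 757 were at least 2-fold higher and 2475 at least 2-fold lower. Uncentred values gave 5 higher and 1406 lower, the 6-array fit without a dye term gave 11 and 325, and loess gave 40 and 320. The count was 329 without array 1, 186 without array 2, 222 without array 4 and 488 without array 5. Of all probes, 725 were called both here and between RNA samples 2 and 1, with RNA sample 2 above both others in 470 and below both in 255. Independent lists of these lengths share 219 probes, but the fitted differences share arrays, which raises the overlap. The pair averages of 2 minus 1 and 3 minus 2, from separate arrays, correlated across probes at r = -0.60 (Spearman's rho -0.62), where 3 RNA samples that differ equally from one another give -0.5 without measurement error. Those of 2 minus 1 and 3 minus 1 correlated at -0.22, where such samples give 0.5, and those of 3 minus 1 and 3 minus 2 at 0.40, where they also give 0.5. Over all probes with floor values the first correlation was -0.24, and it was -0.62 without array 1, -0.37 without array 2, -0.41 without array 5 and -0.61 without array 6. With an array left out, the lone array of its pair borrowed its dye effect from the other pairs, so these values share arrays. Array 1 and array 2 each taken alone, with no borrowed dye effect, gave -0.46 and -0.48 with the pair 3 and 2.

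**Figure D3:**
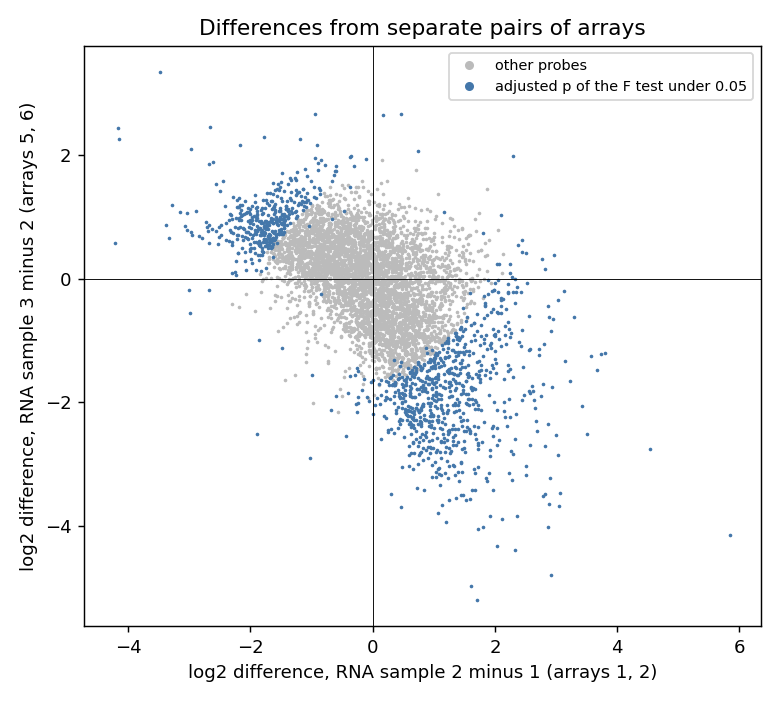
Differences measured on separate arrays. Each point is 1 of the 5431 probes, with the average log2 difference of RNA samples 2 and 1 on arrays 1 and 2 on the x axis and that of RNA samples 3 and 2 on arrays 5 and 6 on the y axis, and blue points passed the F test. The points run from the upper left to the lower right, with r = -0.60.

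Between RNA samples 3 and 1, no named gene passed the threshold. The common standard error of 0.43 exceeded the SD of the pair averages here, 0.31 over the tested probes. The smallest absolute log2 difference called here was 1.69, against 1.11 for RNA samples 2 and 1 and 1.10 for 3 and 2. Few calls here therefore do not show that smaller differences were absent. Among the 173 named probes measured on both arrays, 162 lay within 1.5-fold and 1 reached 2-fold, with its arrays in opposite directions. TSPO had a fitted log2 difference of 0.58 ± 0.43 (SE), with arrays at 1.34 and 0.54. SULT1E1 had 0.47 ± 0.43 (SE), with arrays at -0.006 and 0.43. Over the array, 0 probes were higher and 11 lower in RNA sample 3, none of which has a gene name here. Simulated data with no change in this comparison gave 2.2 calls per run, but with equal noise on all arrays, so this is no baseline for the 11. The fit of single arrays called 0, with 173 probes at an unadjusted p under 0.05 there and 291 in the pair fit. Of 19842 probes measured on both arrays, 78 were at least 2-fold higher and 198 at least 2-fold lower (1.39%). The sample difference had an SD of 0.32 over these probes, against 1.02 for RNA samples 2 and 1 and 0.96 for RNA samples 3 and 2. The dye effect had an SD of 0.59 in this pair, larger than the sample difference, and its 2 arrays correlated at 0.54 before they were turned, where a difference between RNA samples gives a negative correlation. Leaving out array 3 raised the count to 436 and leaving out array 6 to 20, while it was 0 without array 1, 2 or 5 and 1 without array 4. With equal spread it was 108.

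Lineage and maternal genes were measured mainly in the pair of RNA samples 3 and 1. Values are averages of 2 arrays with no test, followed after ± by the gap between the turned arrays divided by 2. This equals the size of the dye effect estimated for the probe in that pair. It is therefore no standard error and does not measure how precise a difference is. KLF4, a pluripotency factor, had a log2 difference of -0.10 ± 0.56, and GATA6, a primitive endoderm factor, of -0.21 ± 0.17. The oocyte growth factor BMP15 had 0.12 ± 0.03, and the cytokine LIF had -0.55 ± 0.11. For the apoptosis genes, PMAIP1 had 0.18 ± 0.36 and FAS had 0.04 ± 1.12. The imprinted gene GNAS had -0.31 ± 0.29 and the sex-determining gene SRY had -0.32 ± 0.88. Of markers of other cells, FSHR of granulosa cells had -0.09 ± 0.41, CD4 of T cells -0.31 ± 0.04, and TYROBP of myeloid cells 0.67 ± 0.65. In the pair 3 and 2, FAS had -1.25 ± 0.26, KLF4 -0.46 ± 0.23, GATA6 0.12 ± 0.33, LIF 0.20 ± 0.61, SRY 0.73 ± 0.75, CD4 0.09 ± 1.01 and TYROBP 0.35 ± 0.10. The FAS value lay at the 83.4 percentile of absolute differences in that pair. Among list genes matched by identical symbol, 2 were tested in the loop. INHA of the cumulus and granulosa list passed the F test (adjusted p 0.00593, also 1 of 1 adjusted over the list alone), while SAL1, salivary lipocalin, in the oviduct and uterus list, did not (adjusted p 0.938). In the fit of single arrays INHA had an adjusted F test p of 0.272, and it did not pass without array 1, 4 or 5. IFN-DELTA-1, unmatched to IFND of the conceptus signals list, was also tested and did not pass the F test (adjusted p 0.247). The trophectoderm, cell junction, cell cycle, heat shock, antioxidant, glycolysis, respiratory chain, lipid, ribosomal protein, chromatin, fibroblast and reference gene lists had no probe with an identical symbol and were not analysed here.

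The genes with the next smallest F test p did not pass. SLC22A2 had an adjusted p of 0.0794, OBP, an odorant-binding protein, 0.143, LAMP1, a lysosomal membrane protein, 0.165, ATP5G1, an ATP synthase subunit, 0.179, and ACVR2B, an activin receptor, 0.191. Because embryos differ in sex, genes on the X chromosome were compared with autosomal genes. None of the 3 X-linked genes tested (MAOA, PDZD11 and OBP) passed the F test, against 10 of 53 autosomal genes (Fisher's exact test, 2-sided, p = 1), and with 3 genes a difference could hardly be detected. The dye test called 1 probe, without a gene name here, with a log2 dye effect of 2.51, and 1470 probes had an unadjusted p under 0.05. The fit of single arrays also called 1. The pair-based dye count was 614 without array 1 or 2, 206 without array 3 or 4 and 151 without array 5 or 6, each of which leaves 2 pairs.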

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

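All tests in this part were chosen after the values had been seen. With 6 arrays, chance sets about 1 in 20 such measures apart, and 11 measures of the arrays were examined, several of them related to each other. Array 1 stood far from the other 5 in 3 of them. Its median log2 ratio was -3 over all probes, against -0.11 to 0.64 on the other arrays. It was -2.39 over the probes measured on that array, against -0.10 to 0.64. The reciprocal of a whole number, the mark of a numerator at the floor, made up 41.3% of its ratios, against at most 6.33% on the others. Over the 5431 probes measured on all arrays its median of -2.50 did not stand apart by the same measure.

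A low amount of the RNA sample in the dim channel of array 1 could give such ratios. The same RNA sample was then expected at the floor elsewhere, but its share on the array with the lowest one was 0.623% if the ratios are Cy5 over Cy3 and 2.20% if they are the reverse. On array 2, though, that RNA sample was at the floor or equal to the other channel for 42.1% of probes in either case. The other RNA sample had 38.8% there, and both shares include the 32.5% of ratios equal to 1. The value thus does not tell a dim RNA sample from a dim array. A dye with little signal on every array is also argued against, since the same dye channel was at the floor for 0.343% of probes on array 4. Labelling, hybridisation or scanning of array 1 itself stays open and was not tested, nor was any biological explanation.

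RNA sample 2 stood apart from RNA samples 1 and 3 in the covariance of pair averages that share an RNA sample but no array. The covariance was 0.59 ± 0.03 (jackknife SE over 48 print blocks) for RNA sample 2, 0.12 ± 0.01 for RNA sample 3 and -0.07 ± 0.01 for RNA sample 1. Independent deviations of the 3 RNA samples do not give a negative value. It can arise where RNA sample 1 lies between the others. Independent noise of the dim arrays may not account for it alone, since it predicts about 0 for each, and RNA sample 2 exceeded the larger of the others by 0.46 ± 0.03, or by 0.20 ± 0.03 with the pairs at equal SD, where uniformly smaller differences on arrays 3 and 4 alone predict no excess. Bias that follows the recovered intensity, as the whole cause, is argued against by excesses of 0.42 ± 0.03 and 0.33 ± 0.04 after loess. That intensity lacks any factor common to both channels, so a bias with true brightness may remain and stays open. The F test count went from 952 to 233 of 4843 probes, with 1492 and 1207 at an unadjusted p under 0.05. Prior degrees of freedom were 7.80 after loess, and the cause of the lower count was not tested. Array 1 alone stays open. With array 2 alone for its pair the excess was 0.37 ± 0.04 on the log2 scale but 0.08 ± 0.04 with the pairs at equal SD. Without array 1, 0 probes passed the F test (smallest adjusted p 0.0834, prior degrees of freedom 2.27, 1604 at an unadjusted p under 0.05), and 329 passed between RNA samples 3 and 2. The share of the sum of squares between RNA samples was then 87.6%. The pair averages correlated at -0.62 with a dye effect borrowed in part from arrays 5 and 6. With array 2 alone and no borrowed dye effect the correlation was -0.48. Without array 1, SULT1E1 and TSPO between RNA samples 2 and 1 had 3.03 and -2.92. The extraction or amplification of RNA sample 2 and a difference between the embryos stay open and were not tested.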

How the results depend on the processing

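Handling of floor values over all probes, print-block centring and loess were added after seeing the data; the other alternatives were planned. Counts of probes moved with most choices of model, and the cause was not tested except where fewer probes or arrays entered. In the order F test, RNA samples 2 and 1, 3 and 1, and 3 and 2, the counts of 1184, 1059, 11 and 1123 became 463, 306, 0 and 656 in the 6-array fit with a dye term and 195, 51, 0 and 336 without the dye term. At an adjusted p under 0.01 they were 735, 506, 3 and 656, and with loess 233, 302, 0 and 360, where 1 probe passed between RNA samples 3 and 1 with the same probes centred. Restricted to the 56 named probes they were 14, 15, 0 and 12, which is also the gene-level result, since no gene had several tested probes. With a fold above 1.5 required, the 3 comparisons had 174, 0 and 353. With values as deposited, 2182 probes passed between RNA samples 2 and 1 and 0 between 3 and 1. Between RNA samples 3 and 1, equal spread gave 108, all probes with floor values 4, and leaving out the dimmest probes 18. Between RNA samples 3 and 2, keeping pairs with 1 measured array gave 665 and all probes with floor values 559. Robust moderation, print-block centring and leaving out the probes with the largest dye effect kept all 4 counts within 1.5 times.

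Leaving out 1 array gave 0 to 1813 probes for the F test, 0 to 1328 for RNA samples 2 and 1, 0 to 436 for 3 and 1, and 186 to 1476 for 3 and 2; the lone array of a pair then borrowed its dye effect from the other pairs. The share of the sum of squares between RNA samples, 86.9%, was 92.4% as deposited, 75.3% over all probes, and 76.4% to 91.1% with 1 array left out. The dye test called 1 probe, and 0 as deposited, with equal spread, at 0.01, over all probes and with loess, and 151 to 614 with 1 array left out. List genes past the F test numbered 1, and 0 as deposited, 0 in the 6-array fit and 0 to 1 with 1 array left out. X-linked genes numbered 0 in each alternative run. Over the alternatives of the named genes, a value stayed past the threshold in 104 cases and lost it in 92 with its direction kept. It reversed in 1, HAPLN1 between RNA samples 2 and 1 as deposited (0.0714), where the uncentred median lies at 1.25. TSPO, SULT1E1 and PPYR1 between RNA samples 3 and 2 stayed past the threshold in all alternatives run for them. Set tests on the gene lists and the choice among several probes of a gene were not run. By identical symbol, a list had at most 1 tested gene. Signal is a limit, since 26.6% of probes were measured on all 6 arrays.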

Other observations

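HBE1, an embryonic globin chain, was chosen after its values were seen. It was measured on both arrays of 2 pairs and lay lower in RNA sample 2 than in RNA sample 1, with a log2 difference of -1.76 and arrays at -1.94 and -1.57. It was also lower in RNA sample 3 than in RNA sample 1, by -0.70, with arrays at -0.61 and -0.79. These values have no test, and the absolute difference between RNA samples 3 and 1 lay at the 95.7 percentile of the probes of that pair.

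The 4 probes that carry the name ASIP, the agouti signalling protein, were compared on the 4 arrays that measured all of them. Their log ratios had a mean SD of 0.48, against a median of 0.85 for 10000 random sets of 4 probes, at the 4.98 percentile. The random sets were not matched for brightness or position on the array. The smaller SD can therefore not be credited to the shared gene.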
